A study of Mus musculus with 9 samples.

How the data were processed

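RNA from hearts of 2 month old mice was measured on 9 arrays, 1 heart per array, with 3 wild type, 3 Col4a3-/- and 3 Col4a3-/-OPN-/- hearts. Hearts were snap frozen and total RNA was isolated with a mirVana PARIS kit, per the labels' protocols. The deposited values are log2 signals made by RMA (background correction, normalization across arrays and summary per probe set), per the submitters' processing notes; no software version was given in the sources used here. The labels name a labelling kit for small RNA, while the probe annotation header names an Affymetrix whole-transcript mouse gene array, and the values sit on that gene array. How the RNA was labelled for this array is therefore uncertain, and the values were read as transcript signals.

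The table held 33793 probe sets. The platform annotation gave 23521 of them 1 gene symbol and 1814 several symbols, and 8458 were not listed. Genes were named only from probe sets with 1 symbol, and symbols were updated by gene identifier through a table of assembly GRCm38.p6, which was used for names, RNA classes, chromosome membership and neighbouring genes only. Of the probe sets with 1 symbol, the 13650 with a mean log2 signal above 5.21, the median over all probe sets, were tested; they stood for 13085 genes, and 13586 of them had their identifier in the reference table. Where a gene had several probe sets (424 genes), each was tested by itself, and the one with the highest mean stood for the gene in gene lists. Several probe sets of 1 gene had opposite signs at an unadjusted p under 0.05 in 1, 5 and 0 genes for the 3 comparisons in the order given below.

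The comparisons were Col4a3-/- minus wild type, Col4a3-/-OPN-/- minus Col4a3-/-, and Col4a3-/-OPN-/- minus wild type. All 9 arrays entered 1 limma fit (lmFit and eBayes with an intensity trend, limma 3.58.1 in R 4.3.3), which gave moderated two-sided p-values, adjusted by the Benjamini-Hochberg method at 0.05. A moderated F-test covered any difference among the 3 genotypes. All adjusted p-values of single genes come from limma. An exact permutation test of 3 hearts against 3 cannot give a p below 0.1, so none was run on single genes. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.15 in each comparison. The fit shared 1 spread per probe set among the genotypes, while Col4a3-/- hearts varied more. Their mean Pearson's r within the group was 0.942 to 0.955, against 0.980 to 0.985 in the other groups. Tests with Col4a3-/- hearts may thus be too lenient, and that of Col4a3-/-OPN-/- against wild type too strict. In all values below, ± marks the SD over the 3 hearts of a group, and SE marks the standard error from the fit.

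Of 47 gene lists for pathways and cell types, 46 had at least 3 measured members and were tested with camera at a preset correlation of 0.01. Their p-values were adjusted over the 46 lists. Members were also adjusted over the list alone. As alternatives, camera was run with an estimated correlation between members, and fry tested whether members moved 1 way on balance. Small nucleolar and small Cajal body RNAs and microRNA precursors, named by the reference table, were tested as 2 further classes in the same way. Values for 4 classes had been seen before these 2, which were the ones fixed in advance, were kept.

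The design was written before the data were examined, for an array of mature microRNAs, and its fallback for another set of probe sets was used. The mature microRNA lists and the single microRNAs it named give no values here. The gene lists were written after the array type and the annotation were seen, but before any value was compared between groups. The rule for named genes took up to 10 higher and 10 lower genes past the threshold without overlap between groups, the 10 genes with the smallest p in each comparison, and the 2 highest and 2 lowest members of each list. Genes outside it are named as such.

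Alternatives were renewed quantile normalization, centring of each array, no filter, a stricter filter (1 log2 unit above the median), all probe sets, eBayes without the trend or with robust moderation, array weights, only the arrays compared, the replicate number as a block, and each array left out in turn. A Y-linked signal as a covariate, an atrial signal as a covariate and 1 probe set per gene were added after seeing the data, as were the scalings, the Y-linked covariate, the estimated correlation and the leaving out of each array for the small RNA classes, and an estimated correlation combined with each array left out for the gene lists. The probe sets without a symbol or with several were tested apart (3246 above the median). The fit was tested on simulated data for Col4a3-/- minus wild type with 200 of 13650 probe sets changed: it recovered 24%, 80%, 96% and 98% of those changed by 0.5, 1, 2 and 3 log2 units, with 3 false among 152 calls. A list of smooth muscle markers shifted by -0.5 in simulated data was the only 1 of 46 lists called. Both simulations drew genes as independent and gave all genotypes 1 spread, while the estimated correlation between members of a list reached 0.84 (lung markers). The simulations therefore do not show how often camera calls a list wrongly in these hearts. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.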

Results

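Transcript levels were measured in 9 mouse hearts. Col4a3-/- mice lack a chain of type IV collagen, a protein of basement membranes, and serve as a model of Alport syndrome, an inherited kidney disease. Col4a3-/-OPN-/- mice also lack osteopontin, a secreted glycoprotein encoded by Spp1 that binds integrins. Each genotype had 3 hearts. The title of the series asks about heart failure with preserved ejection fraction in the Alport mouse, and about osteopontin and mitochondria as its drivers. Array medians lay between 5.18 and 5.24 log2 units, and no 2 of the 9 arrays were identical (Pearson's r between 0.936 and 0.986 over the tested probe sets in 36 pairs).

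The targeted genes could not check the labels. The Col4a3 probe set (17214771) was dim, below the level required for testing, and its place relative to the deleted part of the gene is not known here. Its signal was 5.07, 5.31 and 5.52 in wild type replicates 1 to 3, 5.27, 4.96 and 5.19 in Col4a3-/- replicates 1 to 3, and 5.17, 4.87 and 5.26 in Col4a3-/-OPN-/- replicates 1 to 3. Spp1 has no value here, because the annotation used gives no probe set that symbol.

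Hearts of 1 genotype differed in markers of sex and of tissue. Xist, which is expressed from the inactive X chromosome, was at 7.59, 8.50 and 8.56 in Col4a3-/- replicates 1 and 3 and Col4a3-/-OPN-/- replicate 2, where the Y-linked Eif2s3y was at 4.6001, 4.67 and 4.75. The other 6 hearts had Xist between 4.52 and 4.77 and Eif2s3y between 7.998 and 8.39. The labels give no sex. By these markers Col4a3-/- replicates 1 and 3 and Col4a3-/-OPN-/- replicate 2 have the pattern of female hearts, and the other hearts that of males. No wild type heart has the female pattern, so sex is unbalanced across the genotypes and partly confounded with each comparison below. The Y-linked signal varied within Col4a3-/- and Col4a3-/-OPN-/- only, through replicate 2 of each, so its use as a covariate leans on those hearts. Bmp10, an atrial growth factor, was at 5.72 and 7.40 in Col4a3-/- replicates 1 and 3, at 9.17 in replicate 2, and at 9.79 ± 0.05 (SD, n = 3) in wild type. Scgb1a1, a secretory protein of airway cells, and Ucp1 of brown fat reached 12.2 and 11.1 in Col4a3-/- replicate 2. Col4a3-/- replicate 3 stood apart from the other arrays (mean r of 0.943), with Sele at 8.26, Saa3 at 9.10 and Icam1 at 9.63, genes of endothelial activation and the acute phase.

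**Figure D1:**
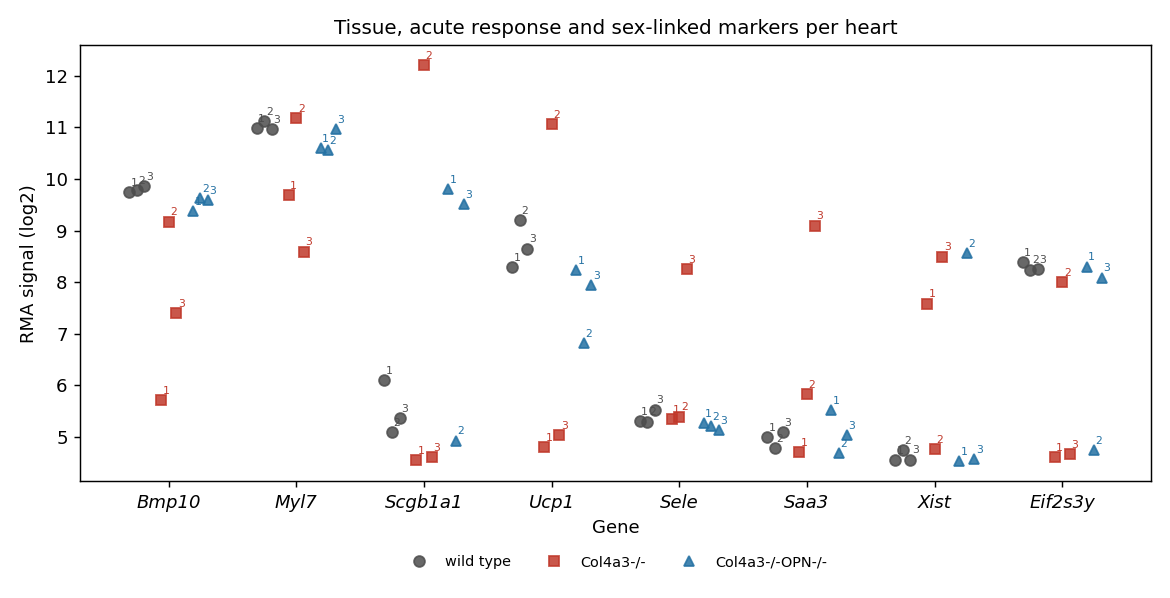
RMA signal (log2, vertical axis) of 8 marker genes in each of 9 hearts, with 1 point per heart, marker shape and colour for genotype and the replicate number beside each point. Col4a3-/- replicate 3 had Sele at 8.26 and Saa3 at 9.10, Col4a3-/- replicate 1 had Bmp10 at 5.72, and Col4a3-/- replicate 2 had Scgb1a1 at 12.2.

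The comparison of Col4a3-/- with wild type hearts asks what accompanies the loss of Col4a3 at this age. Smooth muscle markers were lower as a group. Of 13 measured markers of smooth muscle and pericytes, 11 had a negative difference and 8 passed when adjusted over the list alone, all of them lower, while 0 passed over all genes (median log2 difference -0.46, camera adjusted p = 1.46e-07). With an estimated correlation the list had adjusted p = 0.0727, and with fry 0.00416. Myh11, the smooth muscle myosin heavy chain (probe set 17328368), was at 6.88 ± 0.14 in Col4a3-/- and 7.94 ± 0.10 in wild type (n = 3 each), a log2 difference of -1.07 (SE 0.13, limma adjusted p = 0.0593 over all genes, 5.47e-05 over the list alone). The contractile genes Cnn1 (-1.14), Acta2 (-1.02) and Tagln (-0.89) and the pericyte channel gene Kcnj8 (-0.79) also passed over the list alone, while Des was at 0.07 and Cspg4 at 0.09. Over all left-out arrays the median stayed between -0.48 and -0.39. The median without Col4a3-/- replicate 3 was -0.47 (adjusted p = 8.08e-08), and with the Y-linked signal as a covariate -0.50 (adjusted p = 9.37e-08).

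**Figure D2:**
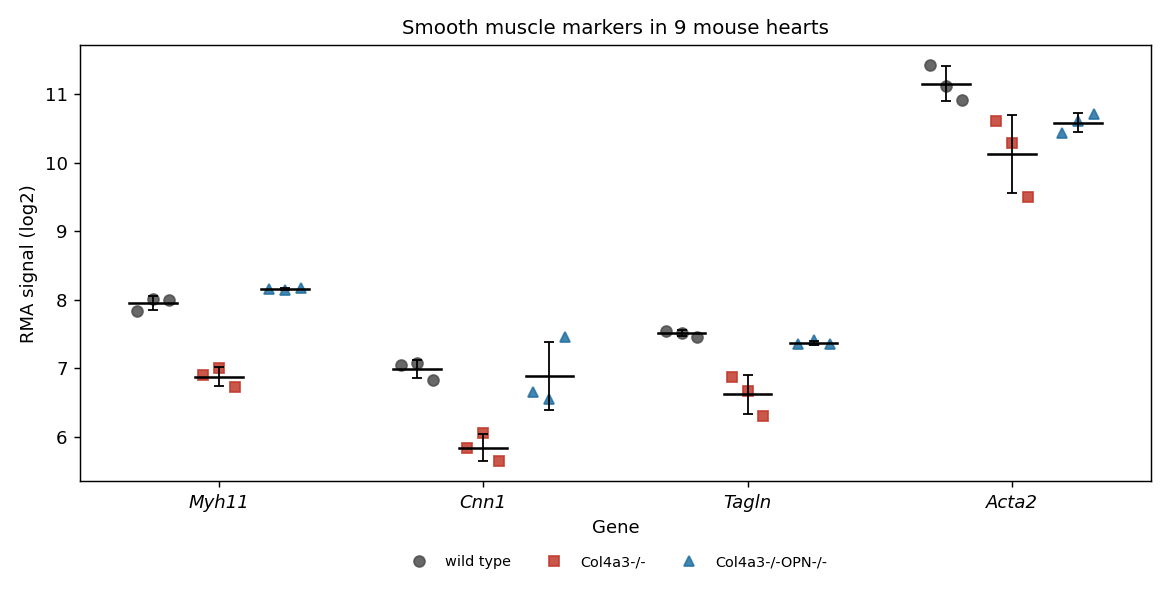
RMA signal (log2, vertical axis) of Myh11, Cnn1, Tagln and Acta2 by genotype, with 1 point per heart and black lines for the mean ± SD of 3 hearts. Mean Myh11 was 7.94 in wild type, 6.88 in Col4a3-/- and 8.15 in Col4a3-/-OPN-/- hearts.

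No single gene passed over all genes in this comparison: limma called 0 of 13650 probe sets, with 1140 at an unadjusted p under 0.05 (326 higher and 814 lower, against 682.5 by chance). Groups did not overlap at 1703 probe sets (12.5%, against 10% by chance). After Myh11, the smallest p belonged to Nop56, a core protein of snoRNA particles (0.997), the small nucleolar RNA Snora33 (0.79), the checkpoint kinase Chek2 (-0.67), the interferon-induced Rsad2 (-0.83), the glutamate transporter Slc17a7 (-1.40) and Tagln (-0.89), each with limma adjusted p = 0.209. The other probe sets of Nop56 had -0.13 and 0.03. Itga8 (-0.99, adjusted p = 0.240), Uprt (-0.80, 0.246) and the imprinted gene Mest (-0.87, 0.300) followed. The count was 1 without wild type replicate 1, 4 without Col4a3-/- replicate 1 and 6 without Col4a3-/- replicate 2.

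Besides smooth muscle, 8 of the 46 lists passed with camera in Col4a3-/- against wild type hearts, and 0 of all 46 with an estimated correlation (smallest adjusted p = 0.0727). Atrial markers were lower (median -0.46, adjusted p = 6.86e-05, and adjusted p = 0.853 with an estimated correlation), with 5 of 13 lower when adjusted over the list alone, among them Bmp10 (-2.36), Sln (-1.01), Dkk3 (-0.74), Myl4 (-0.71) and Nppa (-0.46). The low atrial signal lay in Col4a3-/- replicates 1 and 3, which also had high Xist, and left-out arrays gave medians from -0.61 to -0.32. Col4a3-/-OPN-/- replicate 2, the other heart with high Xist, had Bmp10 at 9.63. Genes of inflammation and acute response were higher (median 0.32, 21 of 24 positive, 0 past over the list alone, adjusted p = 1.77e-05), with Serpina3n at 1.59 and Sele at 0.96. Saa3 was at 6.54 against 4.96 in wild type hearts, below the 5.21 that a probe set's mean over all arrays had to pass, so the size of its difference is uncertain. Without Col4a3-/- replicate 3 this median was 0.11 (adjusted p = 0.0696), and without Col4a3-/- replicate 1 it was 0.57. Interferon response genes were lower (median -0.31, 17 of 18 negative, adjusted p = 4.73e-04), with Gbp7 (-0.94) and Rsad2 (-0.83) past over the list alone, and their median was -0.14 without wild type replicate 3 (adjusted p = 0.138), -0.12 without Col4a3-/- replicate 3 (adjusted p = 0.0856) and -0.42 at its lowest. Macrophage markers were higher (median 0.21, 15 of 18 positive, 0 past over the list alone, adjusted p = 4.01e-04), led by Cd14 (1.05), Gpnmb (0.74) and Cd68 (0.52), with a median of 0.05 without Col4a3-/- replicate 2 (adjusted p = 0.188) and up to 0.28 without the others. Col4a3-/- replicate 2 was also the heart with Scgb1a1 at 12.2 and Ucp1 at 11.1. With an estimated correlation, the inflammation, interferon and macrophage lists each had adjusted p = 0.853.

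Lists for calcium handling (median -0.23, 23 of 27 negative, adjusted p = 0.0150) and the tricarboxylic acid cycle (median -0.12, 20 of 24 negative, adjusted p = 0.0438) were lower in Col4a3-/- hearts, and lung (median 1.003, 4 of 4 positive) and liver markers (median 0.28, 5 of 5 positive, both adjusted p = 0.0482) were higher. None of their members passed over the list alone, and each list had adjusted p = 0.853 with an estimated correlation. The lowest members were the calcium pump regulator Sln (-1.01) and Ogdhl, an oxoglutarate dehydrogenase (Col4a3-/- hearts at 4.83 on average, below 5.21, against 6.55 in wild type), and the highest were Scgb1a1 (1.60) and the albumin gene Alb (2.13). Sln, also an atrial marker, was at 9.99 and 10.4 in Col4a3-/- replicates 1 and 3 and at 11.3 in replicate 2. It was at 11.6 on average in wild type, so less atrial tissue was not told apart from lower calcium handling. Ogdhl stepped among wild type hearts, at 5.06 in replicate 1 and at 7.45 and 7.14 in replicates 2 and 3. The tricarboxylic acid cycle list was not tested without Ogdhl. Lung and liver markers lost their calls under both other scalings (adjusted p = 0.0924 for each after renewed quantile normalization, 0.140 and 0.130 with centred arrays), and the tricarboxylic acid cycle with centred arrays (0.141). Of the 4 lung markers 2 had wild type means below 5.21, so the size of the lung median is uncertain. Lung markers rested on Col4a3-/- replicate 2, without which their median was 0.0149 (adjusted p = 0.811). With the Y-linked signal as a covariate, calcium handling had a median of -0.18 (camera adjusted p = 0.232) and the tricarboxylic acid cycle -0.07 (0.179). Liver markers then had 0.00811 (0.725), while lung markers had 2.56 (8.29e-14). That covariate leans on Col4a3-/- replicate 2, the only Col4a3-/- heart with a high Y-linked signal, on which lung markers also rested. Without Col4a3-/- replicate 3, calcium handling had a median of -0.08 (adjusted p = 0.420), the tricarboxylic acid cycle -0.06 (0.443) and liver markers -0.11 (0.810). Calcium handling had -0.13 without wild type replicate 1 (adjusted p = 0.122), and its highest camera adjusted p in any setting was 0.939. The tricarboxylic acid cycle had adjusted p = 0.0992 and 0.121 without wild type replicates 2 and 3, 0.0533 without Col4a3-/- replicate 2 and 0.05003 without Col4a3-/-OPN-/- replicate 3. Lung markers had 0.0690, 0.0829 and 0.121 without wild type replicates 1 to 3, with medians from 0.96 to 1.06, liver markers had 0.0690 and 0.146 without wild type replicates 1 and 3, and both had 0.0513 and 0.05003 without Col4a3-/-OPN-/- replicates 1 and 3.

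Apart from the tricarboxylic acid cycle, mitochondrial lists did not pass with all arrays in Col4a3-/- against wild type hearts. Subunits of respiratory complex I had a median of -0.02 over 33 genes (adjusted p = 0.781), complexes II to IV 0.01 over 27 genes (adjusted p = 0.451) and ATP synthase -0.01 over 15 genes (adjusted p = 0.884), and no member passed over its list alone. The tests of complex I and ATP synthase pointed higher, against the sign of their medians. Without Col4a3-/- replicate 3, the heart that stood apart, complex I was higher (median 0.06, adjusted p = 0.0362) and so were complexes II to IV (median 0.07, adjusted p = 0.0137), each with adjusted p = 0.826 with an estimated correlation. Over all left-out arrays their medians ranged from -0.12 to 0.06 and from -0.06 to 0.07. Fatty acid oxidation genes had a median of -0.10 (adjusted p = 0.450) and genes of mitochondrial biogenesis and dynamics -0.06 (adjusted p = 0.867). Fibrosis and matrix genes had a median of -0.15 over 43 genes (adjusted p = 0.243), with Acta2 (-1.02), Fmod (-0.88) and Comp (-0.85) lower and the protease gene Mmp3 higher when adjusted over the list alone. Mmp3 was at 5.14 in wild type hearts, below 5.21, so the size of its difference is uncertain. Fibrosis genes had a median of -0.26 without wild type replicate 3 (adjusted p = 0.0391, and 0.952 with an estimated correlation), -0.28 without Col4a3-/- replicate 2 (6.62e-04, and 0.557) and -0.0000569 without Col4a3-/- replicate 3 (0.949). Hypertrophy genes had a median of -0.16 (adjusted p = 0.450), basement membrane genes -0.11 (adjusted p = 0.375) and cardiomyocyte markers -0.04 (adjusted p = 0.945). Without Col4a3-/- replicate 2, hypertrophy genes had a median of -0.20 (adjusted p = 0.0292, and 0.557 with an estimated correlation) and basement membrane genes -0.27 (0.0116, and 0.668). Among integrins and osteopontin receptors (median -0.03, adjusted p = 0.945), Itga8 (-0.99) passed over the list alone. Endothelial markers had a median of -0.15 over 14 genes (adjusted p = 0.213), of -0.35 without Col4a3-/- replicate 3 (adjusted p = 4.25e-04, and 0.802 with an estimated correlation) and of -0.00604 without Col4a3-/- replicate 1 (adjusted p = 0.954).

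**Figure D3:**
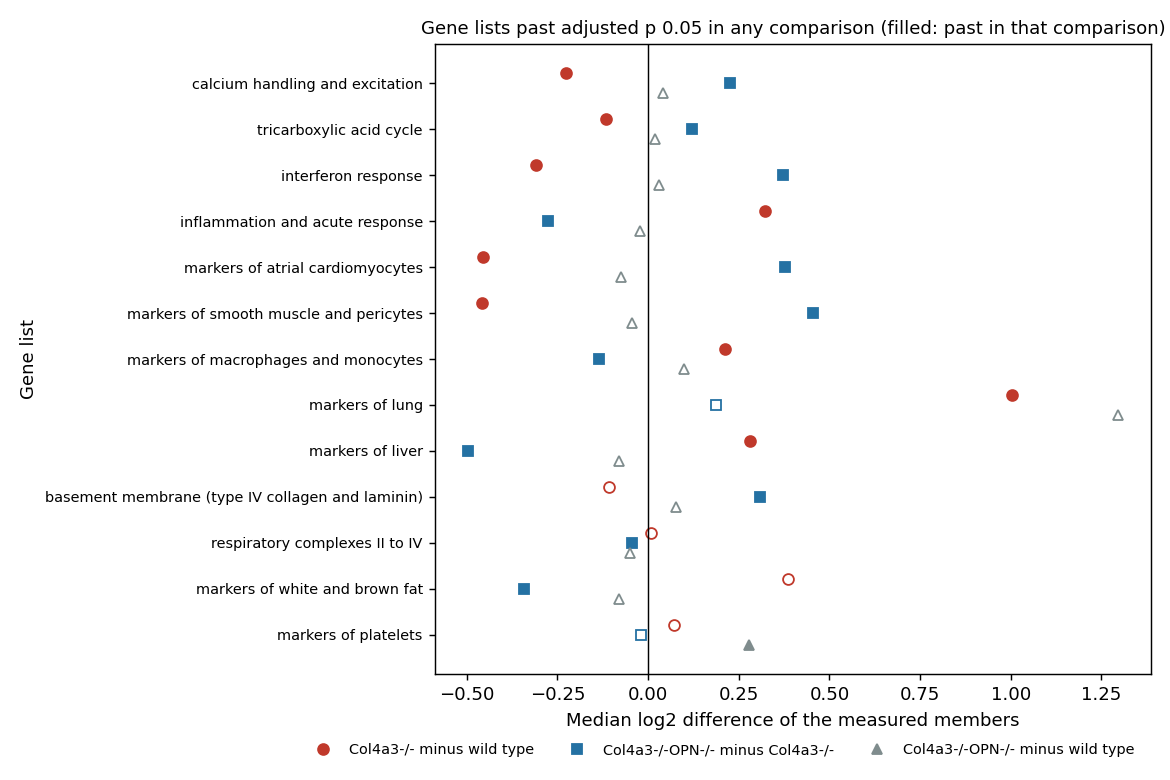
Median log2 difference of the measured members (horizontal axis) for each gene list past adjusted p 0.05 by camera in any comparison, with 1 symbol per list and comparison, filled where it passed. Smooth muscle markers lay at -0.46 for Col4a3-/- minus wild type, 0.46 for Col4a3-/-OPN-/- minus Col4a3-/- and -0.04 for Col4a3-/-OPN-/- minus wild type.

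The comparison of Col4a3-/-OPN-/- with Col4a3-/- hearts asks what the added loss of osteopontin changes. Limma called 6 probe sets, all higher in Col4a3-/-OPN-/- hearts and without overlap between the groups. Myh11 rose 2.42-fold, from 6.88 ± 0.14 to 8.15 ± 0.01 (n = 3 each, log2 difference 1.28, SE 0.13, limma adjusted p = 0.0104). Ppbp, a chemokine stored in platelets (probe set 17438963), rose from 5.07 ± 0.26 to 6.63 ± 0.32 (log2 difference 1.56, SE 0.18, adjusted p = 0.0258). Cyp2d22, a cytochrome P450 (17319625), rose by 1.26 (SE 0.16, adjusted p = 0.0305), and Snap91, an adaptor of clathrin coats (17529417), by 1.33 (SE 0.17, adjusted p = 0.0317). Pm20d1, an enzyme of N-acyl amino acids (17217083), rose by 0.89 (SE 0.12, adjusted p = 0.0480), and Cilp, a matrix protein of cartilage and fibroblasts (17518512), by 1.21 (SE 0.17, adjusted p = 0.0482). The Col4a3-/- means of Ppbp (5.07) and Snap91 (5.06) lay below 5.21, so no fold is given for them and the size of their rise is uncertain.

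Below the threshold in Col4a3-/-OPN-/- against Col4a3-/- hearts, the branched-chain aminotransferase gene Bcat2 had a log2 difference of -1.10 (limma adjusted p = 0.0568), and 2610044O15Rik8 (1.23), Slf1 (0.74) and Zfp235 (at 5.61 against 4.94, below 5.21) each had adjusted p = 0.0888. At an unadjusted p under 0.05 there were 1857 probe sets, 1171 higher and 686 lower, and groups did not overlap at 2259 (16.5%, against 10% by chance). The direction of the calls depended on the setting, and they were 4 higher and 1 lower after renewed quantile normalization, 3 higher and 3 lower without Col4a3-/-OPN-/- replicate 3, 7 of 11 higher without Col4a3-/- replicate 1 and 19 of 22 higher without Col4a3-/- replicate 2. The count fell to 0 without Col4a3-/-OPN-/- replicate 1 and with the Y-linked signal as a covariate, to 1 without wild type replicate 3 and to 2 without Col4a3-/- replicate 3, and it was 5 without wild type replicate 2 and 7 without Col4a3-/-OPN-/- replicate 2. Over 21 other settings the log2 difference of Myh11 stayed between 1.16 and 1.34 (adjusted p from 0.00501 to 0.0876), and over the 20 that tested it that of Ppbp stayed between 1.38 and 1.71 (adjusted p from 0.0140 to 0.129). The call was lost in 3 of 21 settings for Myh11, 5 of 20 for Ppbp, 9 of 21 for Cyp2d22 (highest adjusted p = 0.131), 10 of 20 for Snap91 (0.131), 18 of 21 for Pm20d1 (0.21997) and 17 of 20 for Cilp (0.163). With only the arrays compared there were 5 calls, all higher. Of the 6 genes, Myh11 and Cyp2d22 kept theirs (both adjusted p = 0.0453), while Ppbp had 0.0565, Snap91 0.0694, Pm20d1 0.152 and Cilp 0.137. Without a filter Pm20d1 and Cilp each had adjusted p = 0.0557.

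Smooth muscle markers were higher in Col4a3-/-OPN-/- than in Col4a3-/- hearts (median 0.46, 12 of 13 positive, camera adjusted p = 5.57e-06, and adjusted p = 0.128 with an estimated correlation), and 7 passed when adjusted over the list alone, with Cnn1 at 1.05, Tagln at 0.76, Kcnj8 at 0.68 and Notch3 at 0.60. In all, 11 of 46 lists passed with camera, 0 with an estimated correlation (smallest adjusted p = 0.128) and 2 with fry. Atrial markers were higher (median 0.38, 13 of 13 positive, adjusted p = 2.76e-04), with Bmp10 (2.10), Dkk3 (0.54) and Nppa (0.38) past over the list alone. Interferon response genes were also higher (median 0.37, 17 of 18 positive, adjusted p = 7.23e-05), with Ifit2 (1.03), Gbp7 (0.93) and Rsad2 (0.72) past over the list alone. Genes of inflammation and acute response were lower (median -0.28, 21 of 24 negative, 0 past over the list alone, adjusted p = 3.61e-05), with Selp at -1.08. Saa3 and Sele were at 5.08 and 5.20 in Col4a3-/-OPN-/- hearts, below 5.21, so the size of their differences is uncertain. Saa3 and Sele were highest in Col4a3-/- replicate 3, and atrial genes were lowest in Col4a3-/- replicates 1 and 3. The atrial, interferon and inflammation lists each had adjusted p = 0.734 with an estimated correlation. Left-out arrays gave medians from 0.40 to 0.51 for smooth muscle, 0.34 to 0.53 for atrial, 0.23 to 0.47 for interferon and -0.41 to -0.16 for inflammation genes, with the smallest of the interferon and inflammation medians without Col4a3-/- replicate 3.

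Of lists for energy metabolism, the tricarboxylic acid cycle was higher in Col4a3-/-OPN-/- than in Col4a3-/- hearts (median 0.12, 20 of 24 positive, adjusted p = 0.0379). Ogdhl alone passed over the list alone (2.80, SE 0.54, adjusted p = 0.00719, and 0.127 over all genes). Ogdhl was at 4.83 in Col4a3-/- hearts, below 5.21, so the size of this difference is uncertain. It also stepped among wild type hearts (5.06 in replicate 1, 7.45 and 7.14 in replicates 2 and 3), and the list was not tested without it. Respiratory complexes II to IV were lower (median -0.04, 18 of 27 negative, 0 past over the list alone, adjusted p = 0.0379), with Cox7b at -0.41 and Uqcr11 at -0.34. The tricarboxylic acid cycle and complexes II to IV each had adjusted p = 0.734 with an estimated correlation. Complex I had a median of -0.03 (adjusted p = 0.117), ATP synthase a median of 0.03 with a mean of -0.00410 and a test that pointed lower (adjusted p = 0.541), and fatty acid oxidation 0.11 (adjusted p = 0.0528, with 2 members past over the list alone, among them Hadhb at 0.48). Complex I was lower without Col4a3-/- replicate 3 (median -0.12, adjusted p = 4.93e-04) or replicate 2 (-0.08, 0.0295) and without Col4a3-/-OPN-/- replicates 2 and 3 (both -0.06, 0.0386 and 0.0483), and fatty acid oxidation was higher without Col4a3-/- replicate 3 (0.07, 0.0275) or Col4a3-/-OPN-/- replicate 1 (0.16, 0.00115). Without Col4a3-/- replicate 3, complexes II to IV had a median of -0.13 (adjusted p = 3.62e-04). With an estimated correlation no left-out array gave any of these 3 lists an adjusted p below 0.674. Endothelial markers had a median of 0.26 (adjusted p = 0.0584, and 0.734 with an estimated correlation), of 0.34 without Col4a3-/- replicate 3 (adjusted p = 4.93e-04, and 0.692 with an estimated correlation), of 0.35 without Col4a3-/-OPN-/- replicate 3 (0.0121, and 0.703) and of 0.22 without Col4a3-/- replicate 1 (0.758). Centring each array moved the median of all tested probe sets in this comparison from 0.04 to -0.07, and with it the tricarboxylic acid cycle to 0.01 (adjusted p = 0.197) and smooth muscle to 0.34 (adjusted p = 8.37e-07). Complexes II to IV had adjusted p = 0.146 after renewed quantile normalization. With the Y-linked signal as a covariate they had a median of -0.01 (camera adjusted p = 0.131), and the tricarboxylic acid cycle had 0.10 (0.0445). Fatty acid oxidation (0.13, 0.0358) and endothelial markers (0.28, 0.0223) passed with that covariate. The tricarboxylic acid cycle had adjusted p = 0.0521 and 0.382 without Col4a3-/- replicates 2 and 3 and 0.111 without Col4a3-/-OPN-/- replicate 3, and complexes II to IV had 0.802 and 0.370 without replicate 1 of Col4a3-/- and of Col4a3-/-OPN-/-, with medians of 0.04 and 0.01.

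The remaining 5 lists past camera's threshold in Col4a3-/-OPN-/- against Col4a3-/- hearts were basement membrane (median 0.31, 16 of 19 positive, adjusted p = 0.0283) and calcium handling (0.23, 24 of 27 positive, adjusted p = 0.0196), both higher, and macrophage (-0.14, 12 of 18 negative, adjusted p = 0.0372), fat (-0.34, 10 of 12 negative, adjusted p = 0.0430) and liver markers (-0.50, 5 of 5 negative, adjusted p = 0.0115), all lower. The laminin gene Lama5 had 0.48, the proteoglycan genes Hspg2 and Agrn each 0.47, and Col4a1 0.00. Cacna1g, a T-type calcium channel gene (0.86), was the 1 member of calcium handling past over the list alone, and the other 4 lists had 0. Each of the 5 lists had adjusted p = 0.734 with an estimated correlation. Fat markers lost their call under both other scalings (adjusted p = 0.106 and 0.197) and macrophage markers with centred arrays (0.0884). With the Y-linked signal as a covariate, basement membrane lost its call (median 0.18, camera adjusted p = 0.108). Calcium handling and liver markers kept theirs (each 0.0445), and macrophage and fat markers had medians of -0.29 (1.45e-05) and -0.73 (5.44e-06). That covariate leans on Col4a3-/- replicate 2, the only Col4a3-/- heart with a high Y-linked signal. Macrophage and fat markers both lost their call without that heart. Basement membrane had medians of 0.22 and 0.17 without Col4a3-/- replicates 1 and 3 (adjusted p = 0.317 and 0.0653) and 0.19 without Col4a3-/-OPN-/- replicate 1 (0.252), and without Col4a3-/- replicate 3 calcium handling had 0.13 (0.339) and liver markers -0.13 (0.503). Macrophage markers had 0.609 without Col4a3-/- replicate 2 (median 0.01) and 0.272 and 0.0817 without Col4a3-/-OPN-/- replicates 2 and 3 (medians 0.00164 and -0.15), and fat markers 0.111 without Col4a3-/- replicate 2 (median 0.30) and 0.161 and 0.0782 without Col4a3-/-OPN-/- replicates 1 and 2.

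Col4a3-/-OPN-/- hearts were compared with wild type to see what remained different when both genes were lost. Platelet markers were higher (median 0.28, 4 of 5 positive, camera adjusted p = 0.00144, and adjusted p = 0.248 with an estimated correlation), and 2 passed when adjusted over the list alone. Left-out arrays kept the call with medians from 0.08 (without wild type replicate 3) to 0.40 (without wild type replicate 2). The 2 members were Ppbp, at 6.63 ± 0.32 against 5.29 ± 0.20 (n = 3 each, log2 difference 1.34, SE 0.18, limma adjusted p = 0.167 over all genes), and Gp9, a platelet glycoprotein, at 6.52 ± 0.13 against 5.81 ± 0.20 (0.71, adjusted p = 0.999). In Col4a3-/-OPN-/- minus Col4a3-/- the platelet list did not pass with camera (median -0.02, 2 of 5 positive, adjusted p = 0.175, and 0.0292 with fry). Smooth muscle markers had a median of -0.04 (adjusted p = 0.986), and Myh11 was at 8.15 against 7.94. No other list of the 46 passed, and the smallest adjusted p among them was 0.123. With 1 array left out, interferon response genes passed without wild type replicate 3 (0.18, adjusted p = 0.00200), fatty acid oxidation without Col4a3-/-OPN-/- replicate 1 (0.11, 7.07e-04), and basement membrane (0.17, 0.0106) and complexes II to IV (-0.07, 0.0232) without Col4a3-/-OPN-/- replicate 3. Lung markers passed without Col4a3-/- replicate 2 (1.30, 0.0143) or Col4a3-/-OPN-/- replicate 2 (1.86, 0.0387), and with an estimated correlation the smallest adjusted p among these was 0.801.

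Limma called 0 of 13650 probe sets between Col4a3-/-OPN-/- and wild type hearts, with 503 at an unadjusted p under 0.05 (258 higher and 245 lower, against 682.5 by chance) and 1801 without overlap (13.2%, against 10% by chance). The fit shared 1 spread among the genotypes, and Col4a3-/- hearts varied most, so this comparison may have been tested too strictly. Chek2 had a log2 difference of -0.78 (adjusted p = 0.167). The olfactory receptor genes Olfr1502 (5.15 in Col4a3-/-OPN-/- against 5.92), Olfr1269 (-0.57) and Olfr417 (4.94 against 5.53), of which Olfr1502 and Olfr417 lay below 5.21 in Col4a3-/-OPN-/- hearts, and Snap91 (0.77), Nedd1 (0.62), Trappc6a (-0.65) and B930095G15Rik (0.72), each had adjusted p = 0.999. The count was 1 without wild type replicate 2 and 3 without Col4a3-/-OPN-/- replicate 2. Over all 3 genotypes the moderated F-test of limma called 2 probe sets, Myh11 and Ppbp, with 1269 at an unadjusted p under 0.05. That count was 4 without Col4a3-/-OPN-/- replicate 2, 3 without wild type replicate 1 or Col4a3-/- replicate 2, 1 without wild type replicate 2 or Col4a3-/-OPN-/- replicate 3, and 0 without wild type replicate 3, Col4a3-/- replicate 1 or Col4a3-/-OPN-/- replicate 1.

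**Figure D4:**
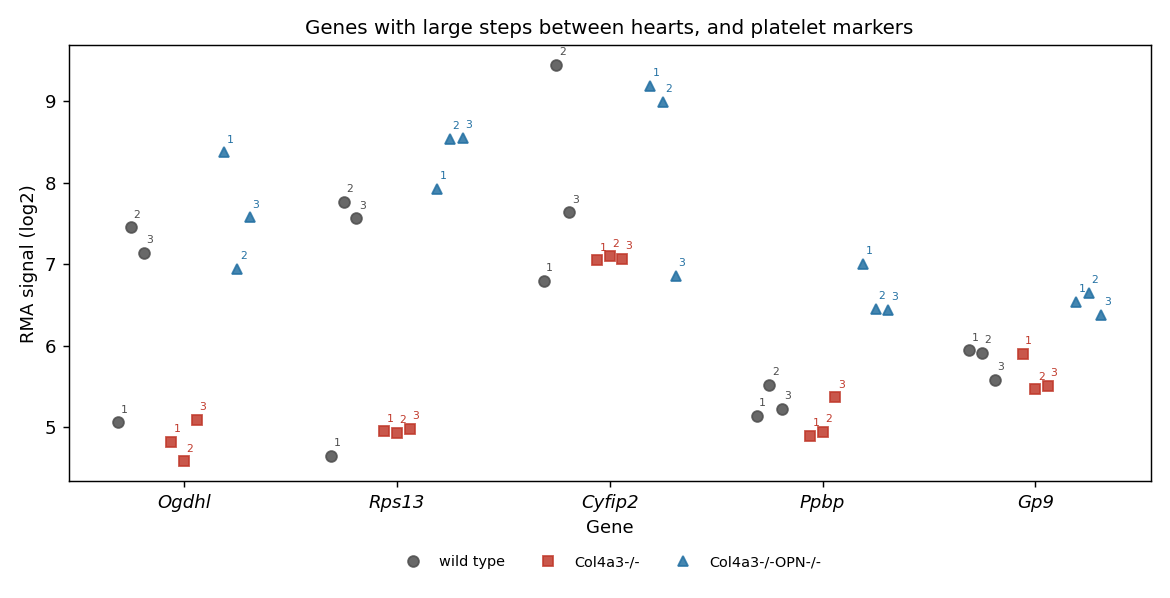
RMA signal (log2, vertical axis) of Ogdhl, Rps13, Cyfip2, Ppbp and Gp9 in each of 9 hearts, with 1 point per heart, marker shape and colour for genotype and the replicate number beside each point. Ppbp was at 6.63 ± 0.32 in Col4a3-/-OPN-/- hearts, while Ogdhl was at 5.06 in wild type replicate 1 and at 7.45 and 7.14 in replicates 2 and 3. Rps13 and Cyfip2 were chosen after their values were seen. The values under Rps13 are those of probe set 17493182 and are not read as the level of that gene.

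Whether differences seen in Col4a3-/- hearts were turned back when osteopontin was also lost was examined across all tested probe sets, which are not independent replicates. The log2 differences of Col4a3-/- minus wild type and of Col4a3-/-OPN-/- minus Col4a3-/- had a correlation of -0.756 and a covariance of -0.0459, and 77.0% of probe sets had opposite signs. Both comparisons use the same Col4a3-/- arrays, which gives a negative relation without any effect. In 1000 simulations of unchanged groups with each group's own spread, the mean correlation was -0.741, the mean covariance -0.0344 (lowest -0.0421) and the share of opposite signs 73.9%. With the spread pooled over the groups instead, the mean correlation was -0.4999, the mean covariance -0.0195 (lowest -0.0233) and the share of opposite signs 66.6%, a difference in covariance of -0.0264. Against each group's own spread the covariance differed from the simulated mean by -0.0115, and without Col4a3-/- replicate 3 by -0.00106 (-0.0378 against -0.0368). Without Col4a3-/- replicate 1 or 2 the covariance was -0.0763 or -0.0752, and these settings were not simulated. With 3 Col4a3-/- hearts the shared arrays could not be divided between the comparisons with at least 2 in each.

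Small nucleolar and small Cajal body RNAs, which guide the modification of other RNAs, were higher in Col4a3-/- than in wild type hearts (median 0.21, 77 of 93 positive, camera adjusted p = 2.95e-14, and adjusted p = 0.129 with an estimated correlation). They were lower in Col4a3-/-OPN-/- than in Col4a3-/- hearts (median -0.36, 89 of 93 negative, adjusted p = 6.95e-23, and 0.0634 with an estimated correlation). Left-out arrays gave medians from 0.11 to 0.33 and from -0.50 to -0.23. Their median in Col4a3-/-OPN-/- minus wild type was -0.09 (adjusted p = 1.73e-05, and 0.348 with an estimated correlation), and 0.000674 (adjusted p = 0.385) without Col4a3-/-OPN-/- replicate 1. The class median per heart was highest, at 8.15 and 8.26, in Col4a3-/- replicates 1 and 3, and with the Y-linked signal as a covariate the difference from wild type turned to -0.03 (adjusted p = 0.0329). Adjusted over the class alone, 3, 11 and 0 members passed in the 3 comparisons, and 0 passed over all genes in each.

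MicroRNA precursors (107 probe sets) had a median of 0.10 in Col4a3-/- minus wild type (79 positive, camera adjusted p = 3.26e-06, and adjusted p = 0.0106 with an estimated correlation) and of -0.15 in Col4a3-/-OPN-/- minus Col4a3-/- (76 negative, adjusted p = 1.75e-08, and 0.00416 with an estimated correlation). In Col4a3-/-OPN-/- minus wild type the median was -0.07 (adjusted p = 0.0144, and 0.132 with an estimated correlation), with adjusted p = 0.148 without wild type replicate 3 and 0.1001 without Col4a3-/-OPN-/- replicate 1. No precursor passed over its class alone or over all genes with limma in these comparisons, and 6, 25 and 10 had an unadjusted p under 0.05. Over all 506 precursors without the filter on dim probe sets, the medians of the 3 comparisons were 0.02, -0.01 and -0.000601.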

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

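Tests chosen only after the result was seen are the circular shifts along chromosomes and the ranges of Ogdhl and the Rps13 probe set among wild type hearts. The reading of endothelial markers beside smooth muscle was also chosen then. Leaving out each array was planned, but the prediction for smooth muscle markers without 1 array was written after the result was seen. The tests with the Y-linked and atrial signals were also added after the data were first examined.

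Probe sets outside the named genes held 2 calls in each comparison with Col4a3-/-OPN-/- hearts. Probe set 17440132, which the annotation used does not list, was at 8.21 ± 0.28 in Col4a3-/-OPN-/- hearts, -2.21 against Col4a3-/- (limma adjusted p = 1.31e-04) and -1.66 against wild type (adjusted p = 0.00209). Probe set 17503531, to which the annotation gives several symbols, was at 5.16 ± 0.30 (n = 3), below the 5.21 required of a mean over all arrays, so the size of its differences of -4.23 against Col4a3-/- (adjusted p = 3.73e-05) and -3.46 against wild type hearts (adjusted p = 2.81e-04) is uncertain. Of probe set 17503531, 1 symbol is that of the Rps13 probe set 17493182, which went the other way (4.95 in Col4a3-/- and 8.34 in Col4a3-/-OPN-/-), so neither is read as the level of that gene. These were the only calls among 3246 such probe sets.

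Smooth muscle markers were lower in Col4a3-/- hearts at camera's preset correlation (adjusted p = 0.0727 with an estimated correlation, and 0.128 for Col4a3-/-OPN-/- against Col4a3-/-), and at the preset correlation the tables argue against Col4a3-/- replicate 3 as the whole cause, since the list had adjusted p = 8.08e-08 without it (median -0.47). The same holds for a trend with sex (adjusted p = 9.37e-08 with the Y-linked signal as a covariate, median -0.50) and for a smaller share of atrial tissue (adjusted p = 3.03e-05 with the atrial signal as a covariate, median -0.52). The Y-linked covariate leans on replicate 2 of Col4a3-/- and of Col4a3-/-OPN-/-, the only hearts that differ from their group in it. A lower share of vessel wall in the dissected tissue, an effect of genotype, and chance stay as hypotheses that no test here decides. Further causes were not examined. Endothelial markers had medians of the same sign as smooth muscle, at -0.15 (adjusted p = 0.213) and 0.26 (adjusted p = 0.0584) in the 2 comparisons with Col4a3-/- hearts, but without Col4a3-/- replicate 3 they were at -0.35 and 0.34 (adjusted p = 4.25e-04 and 4.93e-04, and 0.802 and 0.692 with an estimated correlation) and without Col4a3-/- replicate 1 at -0.00604 and 0.22 (0.954 and 0.758), so they decide nothing on vessels. Over other splits of the 6 hearts the lowest camera adjusted p of the smooth muscle list was 0.0309. For Col4a3-/-OPN-/- against Col4a3-/- it was 0.0155 against 5.57e-06. These lowest values lie under 0.05, so camera also called the smooth muscle list in other groupings. Each other split still set 2 hearts of 1 genotype against 1 of them, so it kept part of any real difference. Such calls are therefore no measure of false calls. With fry the unadjusted p was 9.04e-05 and 1.07e-04 in the real groupings of these 2 comparisons, against 0.232 and 0.241 at the lowest in other splits. The 10 splits are too few for a share under 0.05.

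The turning back of Col4a3-/- differences in Col4a3-/-OPN-/- hearts was weighed against the shared Col4a3-/- arrays and against 1 outlying heart. The covariance of -0.0459 lay below the lowest of 1000 simulated values (-0.0421), which by the prediction would have argued against the shared arrays. That prediction was too strict, because the simulation treats genes as independent and so gives too narrow a range. Without Col4a3-/- replicate 3 the covariance was -0.0378, inside the simulated range down to -0.0495, so that heart may account for the excess in covariance. The share of opposite signs without it was 76.2% against 71.2% simulated, and with all arrays 77.0% against 73.9%. By that measure leaving out the heart did not remove the excess, though the simulated share also rests on independent genes. An effect of osteopontin loss and the shared arrays cannot be told apart with these 3 hearts.

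Genes of chromosome 7 differed more often than others between Col4a3-/-OPN-/- and Col4a3-/- hearts, with 48 of 1026 (4.68%) at an unadjusted p under 0.005 against 22.6 from their share of all genes. Neighbouring genes that move together by chance could give this, since in 10000 circular shifts a share of 0.216 had as high an excess on some chromosome. Sequence carried along with the targeted Spp1 allele was examined through the 100 tested genes nearest Spp1, of which 11 had an unadjusted p under 0.05 against a median of 13 over shifts; that is below the median by less than the spread of the shifts (from 8 at their 5% quantile), and it bears on Spp1's own neighbours alone. Inherited differences between mice of 1 genotype stay open. Ogdhl ranged over 2.39 and Rps13 probe set 17493182, not read as the level of that gene, over 3.12 log2 units among the 3 wild type hearts. The top 1% of tested probe sets began at 0.952. Both ranges met what was predicted for that cause, but both rested on 1 heart, wild type replicate 1 (Ogdhl at 5.06, probe set 17493182 at 4.65). These 2 probe sets had been picked for their steps and not for their chromosome, so their ranges cannot decide on genes of chromosome 7. The labels give no strain, and this cause was left open.

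The results were set against other splits of the same hearts, and every count of splits below includes the real grouping. The 10 splits of 6 hearts are too few for a share under 0.05. Each other split also set 2 hearts of 1 genotype against 1 of them, and so kept part of any real difference. For Col4a3-/- against wild type, 2 of 10 splits had as many probe sets at an unadjusted p under 0.05 (1140, highest other 1529); for Col4a3-/-OPN-/- against Col4a3-/-, 2 of 10 had as many calls (6, highest other 6); for Col4a3-/-OPN-/- against wild type, the 1 of 10 with as many at an unadjusted p under 0.05 was the real grouping itself (503, highest other 472). As many gene lists passed in 8 of 10 splits for Col4a3-/- against wild type (9, highest other 14), in 5 of 10 for Col4a3-/-OPN-/- against Col4a3-/- (11, highest other 19) and in 9 of 10 for Col4a3-/-OPN-/- against wild type (1, highest other 10). For the F-test, 12 of 100 groupings of the 9 hearts, the real one among them, called at least 2 probe sets (highest other 7), so chance was not excluded.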

How the results depend on the processing

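The tests with a Y-linked or atrial covariate, with 1 probe set per gene, and of the small RNA classes with other scalings, an estimated correlation or 1 array left out were chosen after seeing the data. Leaving out each array in turn, the number of calls ranged from 0 to 6 (0 with all arrays) for Col4a3-/- minus wild type, from 0 to 22 (6) for Col4a3-/-OPN-/- minus Col4a3-/-, from 0 to 3 (0) for Col4a3-/-OPN-/- minus wild type and from 0 to 4 (2) for the F-test. The correlation between the 2 sets of differences ranged from -0.837 to -0.692, and gene lists past the threshold from 6 to 13, from 9 to 13 and from 1 to 3. Col4a3-/- minus wild type had 1 call with the stricter filter, without the trend, with robust moderation and with the Y-linked covariate. Col4a3-/-OPN-/- minus Col4a3-/- had 2 calls with centred arrays, the stricter filter and array weights, and 0 with the Y-linked covariate; with that covariate Myh11 went from 1.28 to 1.24, and the fit has 1 residual degree of freedom fewer. Col4a3-/-OPN-/- minus wild type had 2 calls over all probe sets and 1 with array weights or the Y-linked covariate. The F-test had 1 call after quantile normalization, with centred arrays, without a filter, with the stricter filter, without the trend and with the Y-linked covariate, and 4 over all probe sets. Gene lists past the threshold numbered 5 in Col4a3-/- minus wild type with the stricter filter, 0 with an estimated correlation and 1 with fry; in Col4a3-/-OPN-/- minus Col4a3-/- 0 and 2 with the latter pair; in Col4a3-/-OPN-/- minus wild type 2 after quantile normalization or the stricter filter, 6 with the Y-linked covariate, 5 with the atrial covariate and 0 with an estimated correlation. The cause was not tested, apart from filters that change the number tested.

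Some values turned sign. Atrial markers had medians of 0.10 (Col4a3-/- minus wild type) and 0.0186 (Col4a3-/-OPN-/- minus Col4a3-/-) with the atrial covariate, which holds 4 of their own genes. Liver markers had -0.24 with the atrial covariate and ranged from -0.11 (without Col4a3-/- replicate 3) to 0.44 (without replicate 2) in Col4a3-/- minus wild type, and fat markers from -0.67 (without Col4a3-/- replicate 1) to 0.30 (without replicate 2) in Col4a3-/-OPN-/- minus Col4a3-/-. Small nucleolar and Cajal body RNAs had -0.0329 in Col4a3-/- minus wild type with the Y-linked covariate and 0.000674 in Col4a3-/-OPN-/- minus wild type without Col4a3-/-OPN-/- replicate 1. Their medians of 0.21, -0.36 and -0.0922 lost the call with an estimated correlation (adjusted p = 0.129, 0.0634 and 0.348). Left-out arrays gave 0.11 to 0.33, -0.50 to -0.23 and -0.29 to 0.000674 for this class in the 3 comparisons, and -0.0701 to -0.0457 for microRNA precursors in Col4a3-/-OPN-/- minus wild type. The precursors lost the call there with an estimated correlation (-0.0650, adjusted p = 0.132), after quantile normalization (-0.0656, adjusted p = 0.0502) and without a filter (-0.000601, adjusted p = 0.802), and without a filter in Col4a3-/-OPN-/- minus Col4a3-/- (-0.0115, adjusted p = 0.118). The cause was not tested.

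The replicate numbers did not pair the hearts: deviations of same-numbered hearts correlated between -0.194 and 0.230, and 3 of 9 hearts correlated best with their own number. With the replicate block Col4a3-/-OPN-/- minus Col4a3-/- had 0 calls and the F-test 0, and gene lists past the threshold numbered 6, 12 and 1. Dim probe sets near the median signal of 5.21 limit what can be said of Col4a3.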

Other observations

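Several genes outside the lists above stepped between hearts of 1 genotype; they were chosen after their values were seen, and none was tested further here. Cyfip2 was at 9.45 in wild type replicate 2 and at 9.19 and 8.996 in Col4a3-/-OPN-/- replicates 1 and 2, while the other 6 hearts lay between 6.79 and 7.64. Gdpd3 was at 5.36 and 5.85 in Col4a3-/-OPN-/- replicates 1 and 2 and at 8.08 in replicate 3, against 8.30 ± 0.38 in wild type and 8.80 ± 0.47 in Col4a3-/- hearts (n = 3 each).

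Markers of airway cells also differed between hearts of the same genotype. Scgb1a1 was at 9.81 and 9.52 in Col4a3-/-OPN-/- replicates 1 and 3 and at 4.93 in replicate 2. In wild type hearts Scgb1a1 lay at 5.52 ± 0.52. Ucp1 was at 4.79 and 5.03 in Col4a3-/- replicates 1 and 3, against 8.72 ± 0.46 in wild type.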
